A study of Triticum aestivum and Triticum monococcum subsp. aegilopoides x Triticum urartu with 8 samples.

How the data were processed

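RNA from the first leaf of 1-week-old wheat seedlings grown at 23 °C was labelled with Cy3 and hybridised to 8 single-colour Agilent oligonucleotide arrays, 1 array per sample, per the labels' protocols. The arrays fall into 4 groups of 2: wild-type hexaploid (common wheat) hybrids, hexaploid hybrids with type I necrosis, wild-type diploid hybrids of *Triticum monococcum* subsp. *aegilopoides* and *T. urartu*, and diploid hybrids with type IV necrosis. The series design text takes the wild-type hybrid as the reference in each kind of wheat and speaks of independent experiments. The labels do not say that the 2 arrays of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical.

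The deposited scanner files hold spot intensities made with Agilent Feature Extraction, version 10.10.1.1 with the protocol GE1_1010_Sep10 per the file headers and version 9.5 per the submitters' processing notes. The processed intensity per spot, background-corrected by that software per the file headers, was the starting value. The files also hold flags for spots well above background, saturated spots and outlier spots. The authors' value table of the same arrays was set against these files: in each array it equals the deposited processed intensity times 1 factor, between 0.926 (hexaploid type I necrosis 1) and 3.12 (diploid wild type 2), with a spread of the factor within an array of at most 0.206% over probes with an intensity above 50. Its values are therefore linear and not centred. Leaving out 2% of the probes at each end, the mean of each column is 2501, and the column medians are 335 and 338 (hexaploid wild type), 333 and 327 (type I), 206 and 206 (diploid wild type), and 201 and 189 (type IV). The authors' own test, if any, is not given in the sources used here.

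Each array holds 37826 transcript probes with 1 spot each and 1417 control spots. Control spots were left out of the tests, and 68 probes were left out because a spot was flagged as an outlier on at least 1 array. No transcript spot was saturated. The number of probes well above background was 27437 to 28765 on the hexaploid arrays and 23626 to 24556 on the diploid arrays. For arrays, the number of replicates limits the precision.

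The 4 hexaploid arrays lay on slide 1 and the 4 diploid arrays on slide 2, so slide and kind of wheat cannot be told apart, and levels are not compared between the wheats. Within each slide the groups also differed in position. The type I arrays were at positions 1 and 2 and the hexaploid wild type at 3 and 4. On the other slide the wild type was at 1 and 2 and type IV at 3 and 4. Position and necrosis are thus confounded within each wheat, in opposite order. The wild-type and necrosis arrays of a wheat also come from different hybrids. A change given below for a necrosis type is therefore a difference between hybrids, and other differences of genotype between them cannot be told apart from necrosis.

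For each array, log2 of the processed intensity was taken and the array's 75th percentile of it subtracted; all log2 levels below are on this scale. The fit used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), with a mean for each of the 4 groups, 4 residual degrees of freedom per probe and 1.74 prior degrees of freedom. The contrasts were type I necrosis less hexaploid wild type, type IV necrosis less diploid wild type, and the difference of these effects (type IV less type I). A probe was tested in a comparison if it was well above background on both arrays of at least 1 of its groups, and in the difference if it was tested in either. Calls are at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Calls in both comparisons were compared with Fisher's exact test and with the number that independent lists of the same sizes give. The comparisons share no array, but they share the spread of each probe from 1 fit, so a probe with a small spread is more readily called in both. Probes are also not independent units, so Fisher's exact p describes the overlap across probes only.

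Where a probe was not well above background on any array of a group, the fold is given as "at least": the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own value. Counts of probes changed at least 2-fold, 8-fold or 32-fold use the measured changes and not this bound, unless the bound is named. In simulated arrays the residual spreads of the real fit were shuffled over the probes and were equal in all groups. Changes of 0.5, 1, 2 and 3 on the log2 scale, 50 probes each, were recovered for 12%, 64%, 76% and 94% of the changed probes in the hexaploid comparison (28520 probes tested). The diploid comparison (24631 tested) recovered 12%, 52%, 70% and 84%, with 8 false calls in each comparison. Far fewer probes were changed there than were called in the real arrays, which alters the threshold set by the adjustment. These rates therefore do not give the recovery or the false calls of the reported comparisons.

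The files name probes by contig, clone or sequence number. None of the 37826 identifiers matched the reference gene table used here (assembly IWGSC CS RefSeq v2.1), and 6 probes carry a gene symbol. Of 28 gene lists fixed before the data were examined (defence, photosynthesis, hormone, stress, tissue marker and housekeeping classes among them), 27 matched no identifier, and the list of cold, drought and LEA proteins matched 2, cor47 and Wcor15, of which 1 was tested. The planned tests of gene lists were therefore not run, with none of their alternatives. The rule for naming, also fixed beforehand, took probes past the threshold with both arrays of one group above both of the other, and, as no probe has a described product, at most 2 identifiers that rose and 2 that fell in each comparison: those with the largest changes, or, for changes shared by both necrosis types, the largest smaller change. RD29B and Wcor15 are given in addition, as the symbol probes above background, and were chosen after their values were seen.

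The alternatives fixed beforehand were another background correction (normexp with an offset of 50), other scalings (median, the 75th percentile of probes above background on all arrays, quantile normalization over 8 arrays or within each wheat), the authors' value table, no filter or a stricter filter on dim probes, separate fits per wheat, an intensity trend, robust eBayes, a 2-fold minimum, a replicate block and leaving out each array in turn. The files hold no mean signal, so normexp used the median signal and the local background. Scaling to the E1A spike-in controls (4 control probe sequences, above background in every spot, that hybridise to RNA added before labelling) was chosen after seeing the data. In that fit the prior degrees of freedom were infinite, against 1.74 in the main fit, so every probe was given the same spread. Differences of the controls between arrays are shared by all probes there. Its adjusted p-values and numbers of calls are therefore not comparable with those of the other fits.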

Results

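Hybrid necrosis is the death of leaf tissue in hybrids whose parents are healthy, without a pathogen. The 8 arrays measured leaf transcripts in 2 such hybrids, type I necrosis of hexaploid wheat and type IV necrosis of diploid wheat, each beside a wild-type hybrid of the same kind (n = 2 arrays per group). Arrays of one group correlated at 0.987 to 0.995 over all probes. Between wild type and necrosis the correlations were 0.971 in the hexaploid and 0.925 to 0.941 in the diploid. Of the 37826 transcript probes, 21128 were well above background on all 8 arrays and 6224 on none.

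Before scaling, the necrosis arrays were brighter than their wild type. The 75th percentile of the processed intensity was 1681 and 1734 on the hexaploid wild-type arrays and 2409 and 2222 on the type I arrays. It was 591 and 555 on the diploid wild-type arrays and 1207 and 1509 on the type IV arrays. The E1A spike-in controls, in contrast, differed between the group means by 0.02 (log2, necrosis less wild type) in the hexaploid and by -0.11 in the diploid. Relative to these controls the 75th percentile was 0.41 (1.33-fold) higher in type I and 1.35 (2.55-fold) higher in type IV. The spike-in means were 13.69 to 14.16 on the hexaploid slide and 10.02 to 10.29 on the diploid slide. The hexaploid wild-type arrays themselves had means of 14.16 and 13.69, so the smaller hexaploid shift is under the difference between those replicates. The 100 brightest probes of an array held 28.4% and 28.6% of its signal in diploid wild type and 16.9% and 15.1% in type IV. They held 15.1% and 14.6% in hexaploid wild type and 11.5% and 11.8% in type I. All changes below are relative to the 75th percentile.

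**Figure D1:**
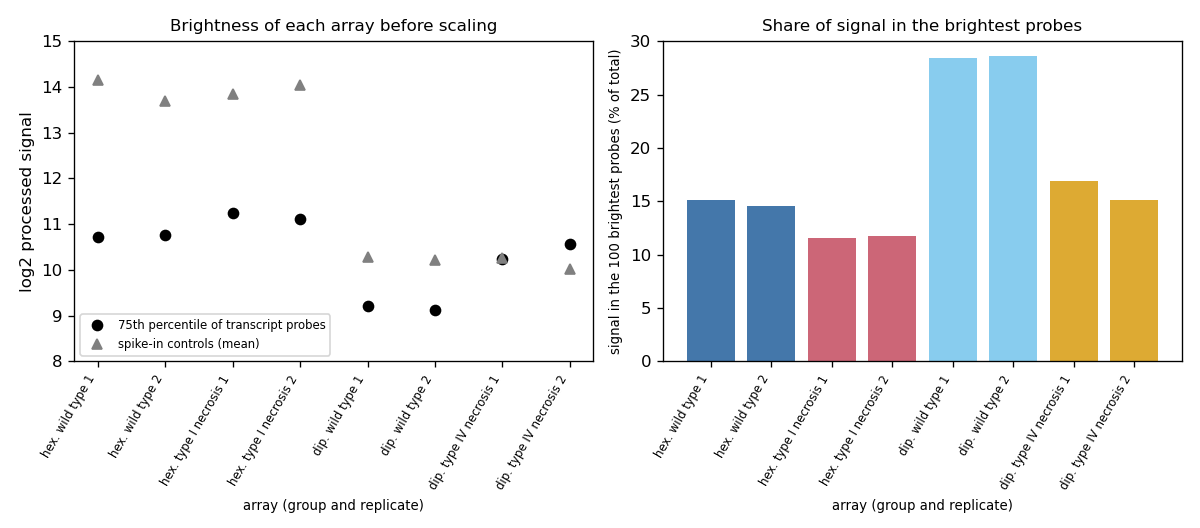
Left: log2 processed intensity at the 75th percentile of the transcript probes (circles) and mean of the spike-in controls (triangles) on each of the 8 arrays. Right: percent of each array's transcript signal held by its 100 brightest probes, coloured by group; the 2 diploid wild-type arrays hold 28.4% and 28.6% and the 2 type IV arrays 16.9% and 15.1%.

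The first comparison asks which transcripts differ between type I necrosis and wild type in hexaploid wheat. Relative to the 75th percentile, large falls outnumbered large rises. Of 28520 probes tested, 6507 rose and 5567 fell, 42.3% of all tested. Among changes of at least 2-fold, 1150 probes rose and 2489 fell. At least 8-fold, 74 rose and 424 fell (22 and 205 with normexp background correction), and at least 32-fold, 6 rose and 128 fell (1 and 58). With spike-in scaling the order of the changes of at least 2-fold turned, to 3174 rises and 1540 falls, and at least 8-fold there were 119 rises and 321 falls. Probes above background on both wild-type arrays and on neither type I array numbered 301, of which 288 were called lower. The converse set, above background on both type I arrays and neither wild-type array, had 535 probes, of which 255 were called higher.

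The probe whsh_allContig461 was at 4.37 ± 0.03 (SD, n = 2) in wild type, a mean unscaled intensity of 35400, and was not well above background on either type I array. It was at least 2220-fold lower in type I (adjusted p = 0.00037). The probe whsh_allContig1037 was above background on all 4 hexaploid arrays and fell by 11.25 on the log2 scale (SE 0.19, adjusted p = 4e-06), from 5.32 ± 0.02 to -5.93 ± 0.13 (SD, n = 2 each). Of the probes that rose, wheat0130Contig5996 reached -1.83 ± 0.01 in type I and was at least 20.7-fold higher than in wild type, where it was not well above background (adjusted p = 1e-05). For wheat0130Contig6895 the level in type I was -1.40 ± 0.01 and the rise at least 27.9-fold (adjusted p = 7.1e-05). These bounds hold for the scanner's own background correction: with normexp, whose offset of 50 raises dim values, the log2 changes of the 4 probes were -9.41, -9.59, 3.26 and 3.11, all called. RD29B, named for a dehydration- and abscisic acid-responsive gene, was above background on all 8 arrays and had a log2 difference of -0.15 in type I (SE 0.13, adjusted p = 0.41), and of 0.27 with spike-in scaling (adjusted p = 0.621).

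The number of calls in this comparison depends on the spread that all 4 groups share. Fitted on the hexaploid arrays alone, 19335 probes were called (10940 rises, 8395 falls). Spike-in scaling, where the spread of the controls raised the median SE from 0.12 to 0.40 and no log2 change under 1.05 was called, gave 4714. Rises outnumbered falls also with median centring (7254 and 4994), quantile normalization over 8 arrays (8085 and 5405) or within each wheat (7719 and 5202) and the authors' value table (7291 and 5248). Without hexaploid wild type 1 or 2 the count was 7035 (3365 rises, 3670 falls) or 7313 (3232 and 4081). Without type I array 1 or 2 it was 6173 (2834 and 3339) or 6220 (2880 and 3340), so in each case, with normexp (6192 and 6622) and with no filter on dim probes (5640 and 5658), falls outnumbered rises.

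The second comparison asks the same of type IV necrosis in diploid wheat. Of 24631 probes tested, 17914 were called (72.7%), 8252 higher and 9662 lower. This count too depends on the spread that all 4 groups share. Fitted on the diploid arrays alone, 15043 were called (6626 higher, 8417 lower), against 19335 of 28520 in type I fitted alone. The larger share called in type IV thus does not hold with separate fits. In the shared fit the median size of the called changes was 0.99 on the log2 scale, against 0.67 in type I. At least 2-fold, 3446 rose and 5401 fell. At least 8-fold, 556 rose and 900 fell (215 and 357 with normexp), and at least 32-fold, 120 rose and 124 fell (20 and 40). In type IV, 939 probes were above background on both necrosis arrays and on neither wild-type array, and 775 of these were called higher. In the converse set, 791 of 804 were called lower.

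The probe MUGEST2003_23lib_Contig19505_653 was not well above background in diploid wild type and stood at 4.06 ± 0.45 (SD, n = 2) in type IV, at least 578-fold higher (adjusted p = 1.5e-06). The probe wheat0130Contig11799 rose by 10.25 on the log2 scale as measured (SE 0.70, adjusted p = 7.3e-05), from -5.39 ± 0.99 to 4.85 ± 1.34, but was above background on only 1 of the 2 wild-type arrays, so the size is not exact. In the other direction, MUGEST2003_23lib_Contig3062_p_233 was at 4.07 ± 0.09 in wild type and not well above background in type IV, at least 810-fold lower (adjusted p = 7.4e-07). For whsh_allContig549, at 3.71 ± 0.05 in wild type, the fall was at least 633-fold (adjusted p = 1.2e-05). With normexp the log2 changes of these 4 probes were 7.32, 7.38, -8.29 and -7.56, all called. Their SEs and adjusted p-values above use the spread shared with the hexaploid arrays. Fitted on the diploid arrays alone, the adjusted p-values were 0.000448, 0.00201, 0.000448 and 0.000863. That of wheat0130Contig11799 was 9.55 or 10.95 without wild-type array 1 or 2 and 9.30 or 11.20 without type IV array 1 or 2, and that of whsh_allContig549 was -10.87 or -9.55 without type IV array 1 or 2. RD29B fell by 0.90 (SE 0.13, adjusted p = 0.0013), but with spike-in scaling its difference was 0.45 and not called (adjusted p = 0.30). Wcor15, a cold-responsive wheat gene, was above background on the 4 diploid arrays and on none of the hexaploid ones. The wheats lay on separate slides, so this does not compare the level of Wcor15 between them. Its log2 difference in type IV was -0.37 (SE 0.26, adjusted p = 0.24), and 0.98 with spike-in scaling (adjusted p = 0.0205, from the fit with infinite prior degrees of freedom and so not comparable). Without type IV array 1 or 2 it was 0.03 (adjusted p = 0.854) or -0.77 (adjusted p = 0.00509). RD29A, cor47, DREB2A and DREB2B were above background on no array.

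The direction of the type IV changes as a whole rests on the scaling. Spike-in scaling gave 16304 rises and 1947 falls, with a median log2 change of 1.30 over the probes tested against -0.05 with the 75th percentile, and normexp gave 6573 rises and 12638 falls. Rises were also the more numerous with median centring (10251 and 8039), quantile normalization over 8 arrays (9509 and 8476) or within each wheat (9638 and 8557) and the authors' value table (9608 and 8660); at least 8-fold the order turned with spike-in scaling (1844 and 239) and with quantile normalization over 8 arrays (681 and 652).

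**Figure D2:**
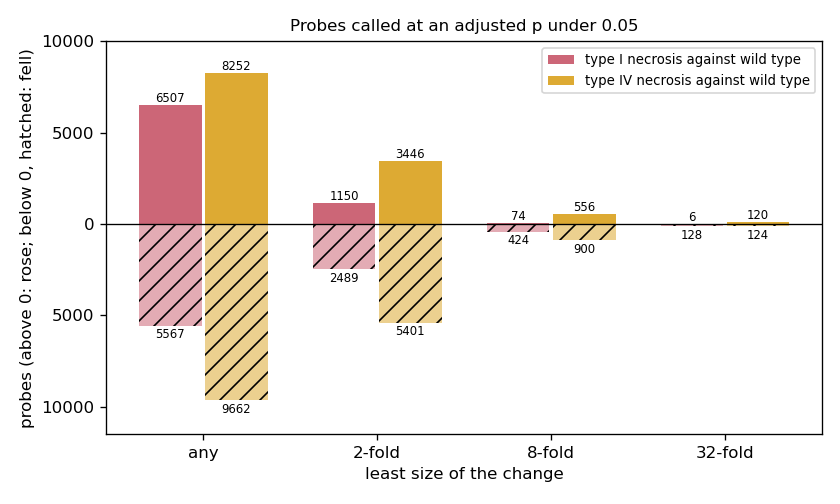
Number of probes called at an adjusted p under 0.05 that rose (above 0) or fell (below 0, hatched), in type I and type IV necrosis, each against its wild type. Bars are for any change and for changes of at least 2-fold, 8-fold and 32-fold as measured, also where a group was below background. Type I had 74 rises and 424 falls of at least 8-fold, and type IV had 556 and 900; with spike-in scaling the type IV numbers turn to 1844 rises and 239 falls.

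The third comparison asks which probes differed from wild type in both necrosis types. Among 23562 probes tested in both, 3233 rose in both and 3580 fell in both, where independent lists of these sizes would share 1897 and 1899. The odds ratios were 3.79 and 6.49; Fisher's exact p for each was below the smallest number the software can hold. Opposite calls were fewer than independent lists give. There were 920 probes that rose in type I and fell in type IV, against 2193 (odds ratio 0.229, p again too small to hold), and 765 that fell in type I and rose in type IV, against 1642 (odds ratio 0.299, Fisher's exact p = 2.55e-216). Across these probes, which are not independent replicates, the log2 fold changes correlated at r = 0.364 (Spearman's rho = 0.475).

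Among changes of at least 8-fold in both types, 115 probes fell in both, against 11 of independent lists (Fisher's exact p = 1.44e-85), and 12 rose in both, against 1 (Fisher's exact p = 2.65e-12). A further 47 fell in type I and rose in type IV, against 6 (Fisher's exact p = 6.64e-27), and 3 rose in type I and fell in type IV, against 1 (Fisher's exact p = 0.123). The probe rwhkv9g07_465 rose 29.4-fold in type I (adjusted p = 0.00011) and at least 122-fold in type IV (adjusted p = 7.8e-06). For MUG004H05R990615 the rises were 17.9-fold (adjusted p = 6.9e-05) and 119-fold (adjusted p = 3.4e-06). The probe MUGEST2003_23lib_Contig438_355 was at least 150-fold lower in type I (adjusted p = 1.2e-05) and 299-fold lower in type IV (adjusted p = 3.3e-06). The probe whsh_allContig461, described above for type I, fell by 8.17 on the log2 scale in type IV (SE 0.92, adjusted p = 5e-04). Its type IV arrays differed widely (-2.97 ± 2.19, SD, n = 2). The SE pools this spread with the smaller one of the hexaploid arrays (SD 0.03 and 0.11), and the fit on the diploid arrays alone gave an adjusted p of 0.0058. Without type IV array 1 or 2 the change was -9.72 or -6.62. With normexp the log2 changes were 4.4 for rwhkv9g07_465 in type IV, 3.22 for MUG004H05R990615 in type I and -5.50 for MUGEST2003_23lib_Contig438_355 in type I. For these 3 probes the diploid arrays fitted alone gave adjusted p-values in type IV of 0.00073, 0.000517 and 0.000507.

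The split of shared calls also turned with scaling. Spike-in scaling gave 2038 probes that rose in both and 637 that fell in both. Without hexaploid wild type 1 or 2 the shared calls numbered 3973 or 4179 in place of 6813, and without type I array 1 or 2 they numbered 3558 or 3576.

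**Figure D3:**
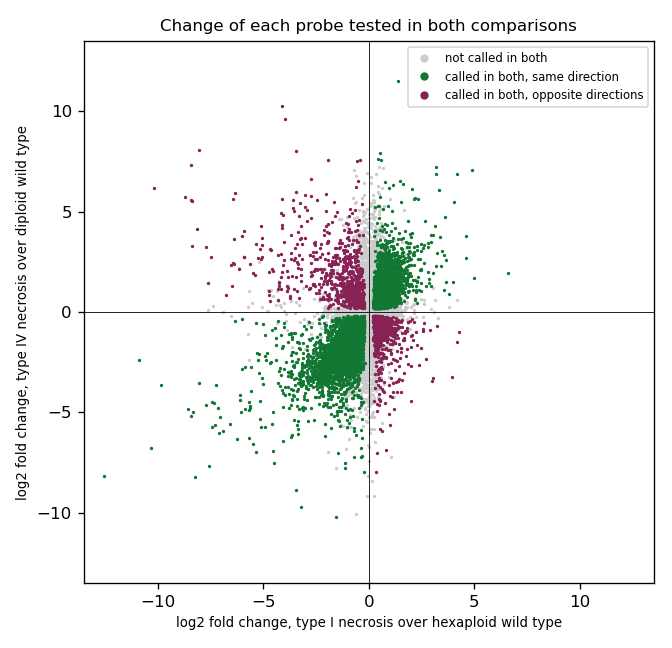
Log2 fold change of type I necrosis over hexaploid wild type (x axis) against that of type IV necrosis over diploid wild type (y axis) for the 23562 probes tested in both, each point a probe. The 6813 probes called in both in the same direction are green and the 1685 called in opposite directions purple; values of probes below background in a group are drawn as measured, and the position of the zero lines depends on the scaling.

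The last comparison tests the difference between the effects of the necrosis types, type IV less type I. Of 29589 probes tested, 15270 differed, 5483 with a more positive and 9787 with a more negative effect in type IV. Only 23562 probes were tested in both comparisons. For the rest, 1 of the 2 effects is a change of values at or near background. The probe wheat0130Contig10206, for example, changed by 0.046 in type I and by -0.509 in type IV, where it was not tested. Its difference was called (adjusted p = 0.0208). Such calls do not show differing responses, and their number was not determined. For differences of at least 8-fold the order turned, with 838 more positive and 555 more negative, and the same order was found with spike-in scaling (1486 and 264) and, in smaller numbers, with normexp (377 and 161).

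The probe whsh_allContig737 was at 1.38 ± 0.25 (SD, n = 2) in hexaploid wild type and not well above background in type I, at least 278-fold lower (adjusted p = 0.00012). In the diploid it rose by 6.21 on the log2 scale (SE 0.51, adjusted p = 0.00015), from 0.80 ± 0.10 to 7.01 ± 1.19. A probe identified by a sequence database number moved in the same directions, at least 74.5-fold lower in type I (adjusted p = 0.00052) and 269-fold higher in type IV (adjusted p = 0.00014). The largest negative differences by the naming rule were those of MUGEST2003_23lib_Contig3062_p_233, which was not well above background on any hexaploid array, and MUGEST2003_23lib_Contig6144_p_150. The second of these fell by 10.05 in type IV (SE 0.61, adjusted p = 4.9e-05), with only 1 of the 2 type IV arrays above background, so this size too is not exact. In type I it had a log2 difference of -0.59 (SE 0.61, adjusted p = 0.48), from 0.99 ± 0.01 to 0.40 ± 0.01 (SD, n = 2 each). That SE pools the spread of the type IV arrays (SD 1.46), so this test does not show that MUGEST2003_23lib_Contig6144_p_150 was unchanged in type I. Its difference between the types had an adjusted p of 0.00059. With normexp the 4 differences were 12.72, 12.03, -7.67 and -6.89, all called. Without type IV array 1 or 2 that of whsh_allContig737 was 15.55 or 17.24, that of the probe with a database number 15.02 or 17.19, and that of MUGEST2003_23lib_Contig6144_p_150 -10.49 or -8.43. With spike-in scaling 6340 probes had a more positive and 1131 a more negative effect in type IV, and normexp gave 4499 and 15110.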

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

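The tests of array position and of unequal labelling were chosen only after the results they bear on were seen, and spike-in scaling was added after seeing the data.

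The effects of the necrosis types differed at 15270 of 29589 probes by the test of the difference itself. These include probes tested in a single wheat, for which a call need not mean differing responses. The 4 named differences (type IV less type I, log2) were 16.39 for whsh_allContig737 (SE 0.73), 16.10 for the probe with a sequence database number (SE 0.93), -11.39 for MUGEST2003_23lib_Contig3062_p_233 (SE 0.21) and -9.46 for MUGEST2003_23lib_Contig6144_p_150 (SE 0.86). Each includes a group with at least 1 array below background, so none of these sizes is exact.

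The first pattern is the set of 1685 probes called in opposite directions. Spike-in scaling adds a constant to all probes of a comparison (0.41 in type I, 1.35 in type IV), so the sign of smaller changes is set by the choice of scaling, which these arrays do not settle. With spike-in scaling 815 of the 1685 probes (48.4%) had opposite signs and 289 (17.2%) were still called in opposite directions. Changes of at least 8-fold exceed the constant, and the 50 probes with such changes in opposite directions kept opposite signs by arithmetic. Of the set, 85.6% were above background on all 8 arrays, so most of its members were not dim by this measure. The filter largely fixed so high a share: 23562 probes were tested in both comparisons, and 21128 transcript probes were above background on all 8 arrays. The share thus does not show that the set holds fewer dim probes than the tested probes in general. Of the 50 probes with opposite changes of at least 8-fold, only 21 were above background on all 8 arrays, so a part of dim values stays open for the rest. The 8 places around each of the 50 did not move with it (median -0.183 in the probe's direction, against 8.76 for the probes themselves). This argues against blemishes or uneven hybridisation over an area of an array. Array position, reversed in order between the slides, would also give opposite changes and cannot be told apart from necrosis here, and a biological difference between the hybrids, which differ in genotype and ploidy, stays open as untested.

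The second pattern is the share of signal in the brightest probes, larger in diploid wild type than in type IV. Less labelled RNA on the wild-type arrays, if it dimmed all probes alike, would leave a share of the array's own signal unchanged, so it could not give this pattern. Unscaled, the 100 brightest diploid probes were brighter in wild type by a median of 0.614 (log2), 78 of 100 of them, which in part restates the larger share. Unequal labelling or washing that acts on all probes alike would leave the share unchanged too. The spike-in controls differed by -0.111, against 1.24 for the 75th percentiles, and the control probe eQC-40, whose target is not known here, moved the other way, by -2.37. These values bear on the brightness of the arrays and do not test the share. An effect of array position common to both slides, where the order is reversed, would turn the order on the hexaploid slide, but there too the wild-type arrays held the larger share, the lower of them exceeding the higher type I array by 2.82 percentage points. A transcript population less dominated by a few abundant species in type IV leaves stays open, as a hypothesis found on these arrays.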

How the results depend on the processing

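Spike-in scaling was chosen after seeing the data; the other alternatives were fixed before. Leaving out each array in turn, where the lone array of its group is assumed to vary like the others, gave 6173 to 16516 calls in type I (12074 with all arrays), 16421 to 19452 in type IV (17914), 10546 to 19290 for the difference (15270) and 3558 to 9625 shared calls (6813). The high ends came without type IV array 1 and the low ends without type I array 1 (in type IV, without diploid wild type 2). A 2-fold minimum, by construction, left 3639, 8847, 8009 and 1845 in the same order. Separate fits per wheat gave 19335 calls in type I, 15043 in type IV and 8346 shared calls. Spike-in scaling gave 4714 calls in type I, 7471 for the difference and 2675 shared ones. It reversed RD29B in type IV to 0.45 and Wcor15 in type IV to 0.98, and moved the uncalled RD29B difference in type I from -0.15 to 0.27; by construction it shifts all probes of an array alike and adds the spread of the controls to every probe. The other alternatives kept each of these totals within 1.5 times, but normexp, whose offset shrinks changes of dim probes, more than halved the calls of at least 8-fold in both types and the difference. The stricter filter on dim probes left several named values untested, among them wheat0130Contig5996 and wheat0130Contig6895 in type I, and these are not counted below for that filter. Among the values of the named probes, 267 kept their direction and their side of the threshold under these alternatives and 173 did so without an array. The exceptions, beside those with spike-in scaling, were RD29B in type I with normexp (-0.27, adjusted p = 0.0372), with quantile normalization within each wheat and without hexaploid wild type 1 (0 in both; -0.29 without wild type 2), and Wcor15 in type IV without type IV array 1 (0.03) or 2 (-0.77, adjusted p = 0.00509); the cause was not tested. The replicate numbers are shared between groups, but the labels do not say that a number marks a shared experiment. Deviations of arrays with the same number correlated at -0.086 in the hexaploid and -0.0057 in the diploid (2 pairs each). With 2 arrays per group the deviations from a group's mean mirror each other. The 2 pairs of a wheat therefore hold the same information, and the values do not settle whether a number marks a shared experiment. With the replicate number as a block 8971, 16592, 12249 and 5090 calls were made. Not run were slide as a block, which coincides with the kind of wheat, the median of a probe's spots, as each has 1, separate fits for the difference, and the list tests, for want of matched names. Signal over background limits 6224 probes, above background on no array.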

Other observations

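The test of position and the spike-in scaling reported here were chosen only after the results were seen.

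Probes can be classed by the first letters of their identifiers. Of the whsh probes, the class with the lowest median in both comparisons, 951 were tested in both. Of these, 416 fell in both (43.7%), against 14.0% of the other probes. They made up 17.5% of the probes that fell at least 8-fold in type I and 3.64% of those tested there, and 45 of the 100 brightest diploid probes. In type I 117 rose and 522 fell, and in type IV 192 rose and 618 fell; with spike-in scaling 35 rose and 248 fell in type I, and in type IV the order turned, with 392 rises and 267 falls. The class was 1 of 39 identifier prefixes with at least 40 tested probes, of which 7 lay below and 9 above the 95% range of random lists in type I, and 14 below and 2 above in type IV. The 7 below in type I were also below in type IV: MUGEST, ncbi, whsh, whv, whva, whvd and whvh. The share that fell in type IV was 64.3% of 140 whv probes and 68.1% of 47 whvh probes, against 63.7% of 970 whsh probes, and in type I it was 31.8%, 39.3% and 50.3%.

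Relative to all probes tested, the median of the whsh probes was -0.57 in type I (95% bootstrap interval -0.70 to -0.51) and -1.04 in type IV (-1.17 to -0.87). Among 10000 random lists matched on level, the whsh median lay at percentile 0 in both comparisons. In type I it was -0.503, and 95% of the lists lay between 0.079 and 0.139. In type IV it was -1.094, and the lists lay between -0.087 and 0.052. Probes of similar level did not fall as far, which argues against level alone. The class was picked for its low median on these arrays, and the lists take probes as independent, so the percentile is not a test of significance. Under quantile normalization the medians relative to all probes tested were -0.556 and -0.717, so the choice of scaling does not account for the relative fall. The sign of the whsh probes' own median in type IV does turn with the scaling (-1.09, and 0.25 with spike-in scaling). An effect of array position common to both slides would give opposite signs on them, and the higher upper bound of the intervals was -0.51. The intervals are for medians over probes, not over arrays. An effect of position that differs between the slides cannot be told apart from necrosis here. What the prefix stands for was not established, and no biological explanation was tested.

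The Agilent control probe eQC-40, which is no part of the comparisons, was above background in all 10 of its spots on every array; what it hybridises to in these leaves is not known here, so what its falls mean is open. Its median log2 intensity was 11.54 and 11.40 in hexaploid wild type against 8.79 and 8.78 in type I, and 12.20 and 12.28 in diploid wild type against 9.88 and 9.86 in type IV. Unscaled, it was 6.44-fold lower in type I and 5.16-fold lower in type IV, and relative to the spike-in controls the log2 differences were -2.71 and -2.26. The SD of its spots was 1.06 on diploid wild type 1 and at most 0.15 on the other arrays. The negative controls averaged between 1.88 and 3.03.

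Some clones have a pair of probes, named with and without a leading r, and some contigs a pair marked p and m. Across 1362 clone pairs the log2 changes in type I correlated at 0.722, and across 986 pairs in type IV at 0.635. For the p and m pairs the correlations were 0.235 (108 pairs) and 0.193 (85 pairs). In hexaploid wild type, 82 of 833 p and m pairs had both probes above background, 304 only the p probe and 159 only the m probe.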
